A study of Mus musculus with 2 samples.

How the data were processed

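Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the transcription factors Smad2 and Smad3, the receptor-activated SMADs of the TGF-beta pathway, were bound in NMuMG cells, an epithelial cell line of the mouse mammary gland. Per the labels' protocols, the cells had received TGF-beta3 at 1 ng/ml for 1.5 h in medium with 10% serum and 10 ug/ml insulin. Per the same protocols, chromatin was precipitated with an antibody that recognises both proteins. The series held 2 samples, 1 anti-Smad2/3 ChIP library and 1 input library of treated cells. Their groups were taken from the sample descriptions. No library of untreated cells and no replicate was analysed here.

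The only processed file was a list of called regions for the ChIP library. Bowtie2 and the mouse genome build mm9 are named in the submitters' processing notes, without a version. The peak caller, its threshold, the role of the input library and any filter on the regions are not given in the sources used here. The name of the deposited file carries abbreviations, among them FDR, that may refer to the caller and its threshold. The labels do not spell them out, and no step is taken as known from them. Each of the 5847 lines gave a chromosome, a start, an end, a running number, a score and a strand. The deposited score was 1000 in every line and the strand had 1 value, so neither ranked the regions. The running number deposited as the region's name went from 1 to 5847 in file order, and whether this order is a rank by significance is not stated. Every start was a multiple of 50 bp and every end was 1 bp below such a multiple, so the authors' positions lie on a 50 bp grid. Positions were read by the convention of the BED format and are printed counted from 1. If the authors' ends are inclusive, each region is 1 bp longer than stated. The file held no read counts, heights or enrichments. The sequencing depth is therefore unknown, and no interval on the strength of a single region could be given.

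The number and width of the regions, their density per chromosome, their spacing and their clusters were computed from the positions. As no chromosome lengths of mm9 were used, density was expressed per Mb of the span between the first and the last region centre of a chromosome. It was set beside the 95% range of 1000 placements of the same number of regions, uniform over all spans. The rule fixed beforehand foresaw such placements per chromosome only where chromosome lengths were given. Their use over spans departs from that rule. Regions were called neighbours within the clustering distance when their centres lay no more than 12.5 kb apart, and a cluster was a run of at least 3 such regions. The number of clusters was set beside the 95% range of 1000 placements of the regions, uniform within the span of their own chromosome. Relations between width, list number and distance to the nearest region were described by Spearman's rho across regions, with a 95% interval from 1000 bootstrap samples of the regions. Shares of regions carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. With 1 ChIP library, regions are not replicates and no p-value was computed. The ranges and intervals describe this list and do not measure the spread between experiments.

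Rules were fixed before the data were examined. With no usable score, the regions named are the 10 widest and the regions of the 5 clusters with the most members, ties going to the shorter cluster. No rule had been set for ties in width, and such ties are stated. The first 10 regions of the list and the densest 1 Mb window were named after their values were seen. The relations planned across regions were those of score, width and distance to the next region. Relations with list number and widths by part of the list were not in that plan. Neither were the shares of clustered regions by width or list order, nor the longest stretches without a region. The alternatives fixed beforehand were the regions at or above the median width, merging of regions that touch or lie within 500 bp, cluster gaps of 5, 25 and 50 kb, clusters of at least 2 or 4 regions, counting regions within the clustering distance once, placement within a region's own 1 Mb window, and leaving out the top 1% of width and list order. The first 2923 regions of the list, merging within 2 kb and leaving out chromosome X were added after seeing the data.

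Comparisons of the regions with genes, gene features, fixed gene lists and sequence motifs had also been planned and were not run. They need the mm9 sequence and annotation, which were not used here. The gene table at hand describes GRCm38.p6, and positions of different builds were not mixed, so no region is assigned to a gene below.

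The cluster and density computations were tested on simulated data. In 18 of 20 simulations of 5847 uniformly placed regions the number of clusters lay within its range. All 200 clusters planted among such regions, which made 6647 regions in all, were recovered. The planted regions stood closer together than the clustering distance, so recovery followed from the definition and checked the computation only. The interval of the density ratio of chromosome X held the simulated ratio in 97% of 200 simulations of 5847 regions. These simulations drew each region independently and at a ratio other than the observed one. They do not show how the interval performs for clustered regions. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.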

Results

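Regions bound by Smad2/3 were determined in NMuMG mouse mammary epithelial cells treated with TGF-beta3 at 1 ng/ml for 1.5 h. One list of regions from 1 anti-Smad2/3 ChIP library was examined, together with the labels of its input library. There were no replicates and no untreated cells, so the list describes occupancy after treatment and holds no measure of its change. Sequencing depth and the read counts behind each region are unknown. All positions refer to mm9, and none of them was assigned to a gene.

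The list held 5847 Smad2/3 regions on the 19 autosomes and chromosome X. The regions were narrow, with a median width of 349 bp, an interquartile range of 249 to 499 bp and extremes of 99 and 1799 bp. Together they covered 2.33 Mb, or 0.0920% of the 2532 Mb between the first and last regions of the chromosomes. Of all regions, 92 were wider than 1 kb and 957 were narrower than 200 bp. None was listed more than once, and the closest edges of neighbouring regions were 51 bp apart.

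The widest region lay on chromosome 19 at 5845351 to 5847149, spanned 1799 bp and was number 1605 in the list. The next widest was a region of 1699 bp on chromosome 3 at 30992501 to 30994199, which was number 4 in the list. On chromosome 18, a region of 1649 bp lay at 42929651 to 42931299 and one of 1549 bp at 25872751 to 25874299. Chromosome 9 carried a region of 1549 bp at 53824501 to 53826049 and one of 1499 bp at 120685001 to 120686499. A further 3 regions measured 1499 bp each and lay on chromosome 7 at 80733351 to 80734849, on chromosome 1 at 43225151 to 43226649 and on chromosome 2 at 93884801 to 93886299. The tenth place was shared by 4 regions of 1449 bp, of which the earliest in the list lay on chromosome 9 at 111489151 to 111490599. Of the 9 regions wider than these, 6 had another region within the clustering distance and 2 belonged to a cluster of at least 3. Of the 4 regions of 1449 bp, all had such a neighbour and 2 belonged to a cluster.

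Regions that came early in the list were wider. The median width was 599 bp (interquartile range 449 to 799 bp) in the first 585 regions and 249 bp (199 to 299 bp) in the last 584. Spearman's rho between width and list number was -0.61 across the 5847 regions, with a bootstrap 95% interval of -0.63 to -0.60. The order of the list was not a simple order of width, since 2 of the 9 widest regions stood among the first 100 and the latest of them was number 2130. Region number 1 lay on chromosome 2 at 168357351 to 168358299, spanned 949 bp and belonged to a cluster of 4 regions. Region number 2 lay on chromosome 4 at 47270851 to 47271849, was 999 bp wide and stood 35.5 kb from its nearest neighbour. Region number 3, on chromosome 1 at 135592151 to 135592999, was 849 bp wide and stood 76.1 kb from its nearest neighbour. The first 10 regions of the list, which were looked up after the data were seen, were 849 to 1699 bp wide, and 2 of them were also among the 9 widest.

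Smad2/3 regions were not spread evenly over the chromosomes. Chromosome X carried 73 regions, or 0.458 per Mb, against 2.43 per Mb on the autosomes. Uniform placement gave 335 to 407 regions on X. The density of X was 0.188 times that of the autosomes (exact 95% interval 0.147 to 0.237). Among the autosomes, chromosome 19 was the densest with 204 regions and 3.56 per Mb, and chromosome 14 the sparsest with 190 regions and 1.68 per Mb, a ratio of 2.12. Chromosomes 8, 9, 11, 13, 15 and 19 lay above the range of uniform placement, and chromosomes 7, 12, 14 and X lay below it. The other 10 chromosomes lay within their ranges. Chromosomes 12 and 13 had similar spans of 117.2 and 116.4 Mb and carried 207 and 359 regions. The median width was 299 bp on X (interquartile range 249 to 399 bp) and 349 bp on the autosomes (249 to 499 bp). The ranges and the interval of the density ratio treat each region as placed independently. With regions within the clustering distance counted once, chromosome 8 (252 regions, range 204 to 264) came to lie within its range, chromosome 10 (259 regions, range 200 to 256) came to lie above it, and the other 18 chromosomes kept their side. All these ranges were drawn over all spans, so the few regions of X lower them for the autosomes. The list held 2.31 regions per Mb of all spans, against 2.43 on the autosomes. Autosomes near an end of their range may change side against the autosomes alone. Examples are chromosomes 8 and 10, and chromosome 6 with all regions (300, range 299 to 367), for which that was not run.

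**Figure D1:**
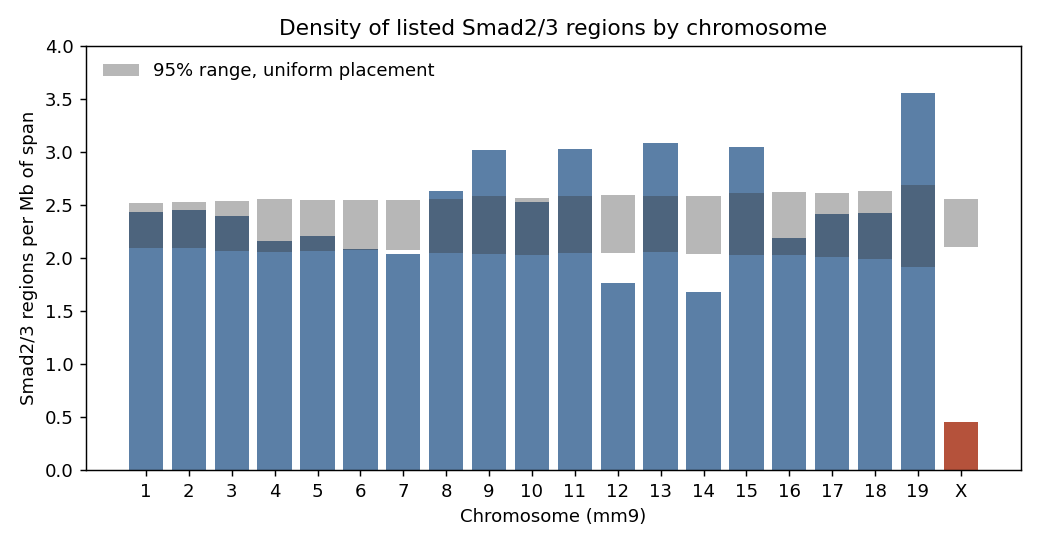
Bars give the number of listed Smad2/3 regions per Mb of span (vertical axis) for each mm9 chromosome (horizontal axis), from 1 ChIP library, and grey bands give the 95% range of 1000 uniform placements. Chromosome X stands at 0.458 regions per Mb, far under its band, and chromosome 19 at 3.56, above it.

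Long stretches without any region were most frequent on chromosome X. Of the 10 longest stretches, 5 were on X, and 4 of these were longer than the longest on any autosome, which measured 11.8 Mb and lay on chromosome 7. The longest ran from 20394500 to 45807100 on X and measured 25.4 Mb. A further 21.0 Mb without a region followed from 45807500 to 66793950. The few regions of X make long stretches on it likelier, and these were not set beside placements of X alone. Uniform placements within chromosomes, pooled over all of them, gave a mean of 0.614 centre distances of 7 to 7.25 log10 bp, against 3 observed. At 7.25 to 7.5 log10 bp they gave a mean of 0.015, again against 3 observed. How far the stretches of X exceed what its density gives was therefore not tested for X by itself. The densest 1 Mb window, which was picked out after the data were seen, lay between 129 and 130 Mb of chromosome 8. It held 28 regions, 16 of them in 4 clusters, where the densest window of a uniform placement held 9 to 12.

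**Figure D2:**
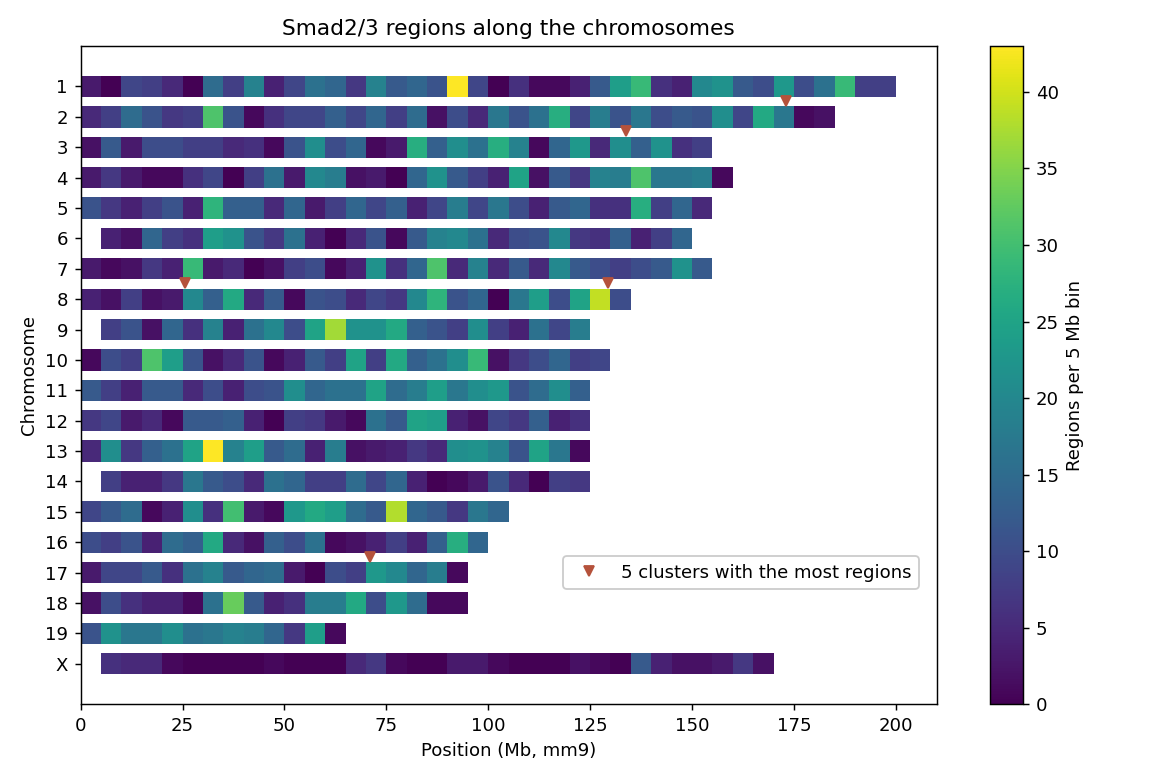
Each row is a chromosome and each block is a 5 Mb bin (position in Mb on the horizontal axis, mm9), coloured by the number of listed Smad2/3 regions, and triangles mark the 5 clusters with the most regions. Most of chromosome X lies at the low end of the colour scale, and 2 of the 5 marked clusters are on chromosome 8.

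Neighbouring regions lay closer together than uniform placement within chromosomes gave. The median distance between neighbouring centres was 96.5 kb, against 275.0 to 289.8 kb in the placements. Of the 5827 neighbouring pairs, 1255 (21.5%) lay within the clustering distance, against 2.68 to 3.52% in the placements. In all, 237 clusters of at least 3 regions were found, and the placements gave 1 to 10 clusters. Placement of each region within its own 1 Mb window gave 17 to 36. The clusters held 812 regions, or 13.9% of the list, and 3675 regions (62.9%) had no neighbour within that distance. Most clusters were small, with 175 of 3 regions, 40 of 4 regions and 22 of 5 to 8 regions. Their median extent was 10.5 kb (interquartile range 5.85 to 14.9 kb). The count rested in part on regions that lie very close together, since merging regions within 2 kb left 98 clusters, against 1 to 9 in placements of the merged regions.

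**Figure D3:**
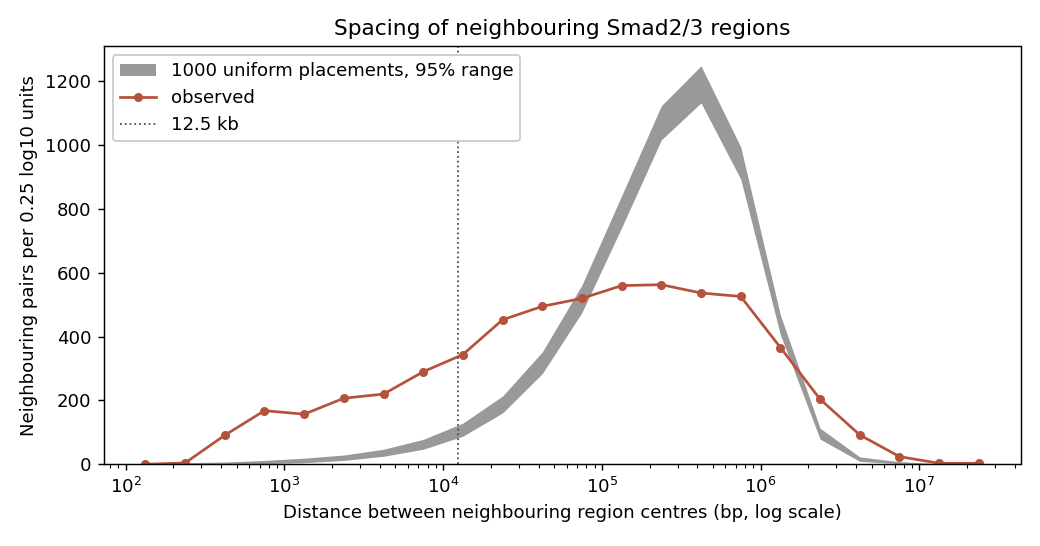
The line gives the observed number of neighbouring region pairs (vertical axis, per 0.25 log10 units) by the distance between their centres in bp (horizontal axis, log scale), and the grey band gives the 95% range of 1000 uniform placements within chromosomes. The dotted line is the clustering distance, and 21.5% of all observed pairs fall to its left, against 2.68 to 3.52% in the placements.

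The cluster with the most regions and the shorter extent lay on chromosome 2 from 173082951 to 173107249. It held 8 regions in 24.3 kb, of which 5.44 kb was covered. Its first 4 regions were 749 to 1399 bp wide and had list numbers between 57 and 590, and the other 4 were 249 to 499 bp wide with numbers from 3057 to 5540. A cluster on chromosome 8 from 25506101 to 25541299 also held 8 regions, in 35.2 kb, none of them wider than 449 bp. Another on chromosome 8, from 129353301 to 129377399, held 7 regions of 299 to 699 bp in 24.1 kb and lay within the densest 1 Mb window. The cluster on chromosome 17 from 71058901 to 71105549 held 7 regions of 149 to 549 bp and, at 46.6 kb, was the longest of all 237. The most compact of these 5 clusters held 6 regions in 6.10 kb, on chromosome 3 from 133897451 to 133903549, and its widest region, at 849 bp, was number 61 in the list. Other clusters also held 6 regions, and this one was taken because it was the shortest of them, by the rule for ties.

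**Figure D4:**
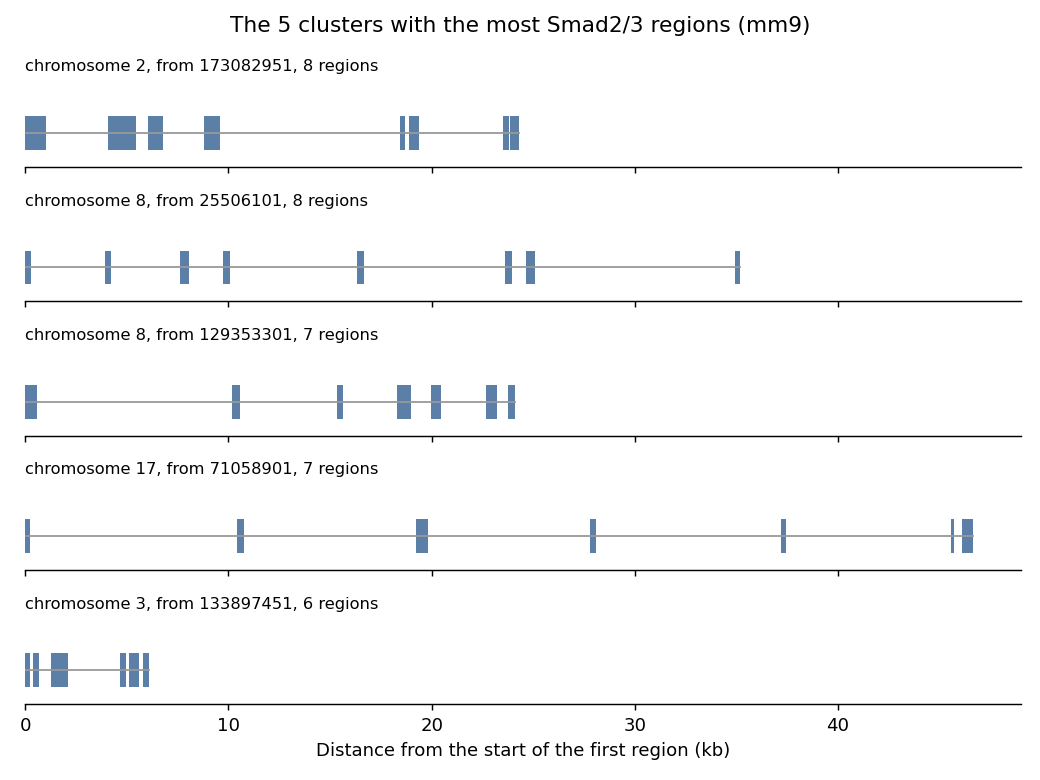
Blue blocks are the listed Smad2/3 regions of the 5 clusters with the most regions, drawn to scale by distance in kb from the start of each cluster (horizontal axis, mm9). The clusters hold 6 to 8 regions, and their extents run from 6.10 kb on chromosome 3 to 46.6 kb on chromosome 17. The cluster on chromosome 3 is the shortest of several with 6 regions, as ties went to the shorter cluster.

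Wider regions were more often part of a cluster. Among the 1601 regions of at least 499 bp, 264 (16.5%, exact 95% interval 14.7 to 18.4%) were in clusters, against 214 (11.6%, 10.2 to 13.2%) of the 1842 regions of at most 249 bp. The same held for the list order, with 16.4% (exact 95% interval 15.0 to 17.7%) in the first 2923 regions and 11.4% (10.3 to 12.6%) in the other 2924. Width and list number were themselves related (rho -0.61), so the result for list order is not independent of that for width. Their relations with spacing were weak across all regions. Spearman's rho with the distance to the nearest region was -0.09 for width (95% interval -0.11 to -0.06) and 0.10 for list number (0.07 to 0.12). The intervals for clusters and distances treat regions as independent. Regions of a cluster share their membership and neighbours can share a distance, so these intervals may be too narrow. On chromosome X, 3 of 73 regions (4.11%, exact 95% interval 0.856 to 11.5%) were in a cluster. This share was not set beside placements at the low density of X. It therefore does not show whether X regions cluster less than their density gives.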

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

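The first 2923 regions of the list, merging within 2 kb and leaving out chromosome X were chosen after seeing the data. No density ratio crossed 1 and no rho changed sign under the alternatives run for it. The median width was 449 bp, against 349 bp, both in the wider regions and in the first part of the list. Keeping regions at or above the median width left 3230, because of ties, and keeping the first part of the list left 2923, both by construction. The density ratios of chromosome X to the autosomes (0.158 to 0.207) and of chromosome 19 to the other autosomes (1.47 to 1.54, from a main value of 1.48) stayed within their intervals. The number of clusters, 237 as defined, was 178 with regions within 500 bp merged, 105 at a gap of 5 kb, 368 at 25 kb, 535 at 50 kb, 917 with at least 2 regions, 62 with at least 4, 70 in the wider regions, 71 in the first part of the list and 98 with regions within 2 kb merged, which follows from the changed definition or the fewer regions. The observed number over the mean of the placements was 44.7, and became 119 at 5 kb, 18.2 at 25 kb, 7.50 at 50 kb, 5.29 with at least 2 regions, 360.5 with at least 4, 69.0 in the wider regions, 105 in the first part of the list, 23.6 with regions within 2 kb merged and 9.27 with placement in 1 Mb windows. Several of these ratios rest on a mean of about 1 cluster or fewer, so their size is not precise, but in all 10 alternatives the observed number lay above the range of the placements. Spearman's rho between width and list number was -0.59 without the top 1% of width and of list order. No region touched another and none lay on M, Y or an unplaced sequence, so these 2 alternatives moved nothing. The alternatives for gene features, gene lists and motifs were not run, as they need an mm9 annotation or sequence. No paired analysis was possible because there is 1 ChIP library, and leaving out a replicate was likewise not possible. The list holds no depth, so a region missing from it cannot be read as unbound.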

Other observations

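Other sparse and dense stretches stood out along the chromosomes. In bins of 5 Mb, the highest numbers were 43 regions at 90 to 95 Mb of chromosome 1 and 43 at 30 to 35 Mb of chromosome 13. After the window on chromosome 8, the densest 1 Mb windows were at 31 to 32 Mb of chromosome 13 with 19 regions and at 30 to 31 Mb of chromosome 16 with 17 regions. On chromosome 14, 0 of 10 equal parts exceeded the median density of such parts on the autosomes (2.33 regions per Mb), although single 5 Mb bins held up to 17 regions. Chromosome 14 was the sparsest autosome, so few such parts follow from its density, and an even spread of its regions was not run. The comparison of chromosome X with uniform placement was chosen after its result was seen. The tests that merge regions within 2 kb, split the list at number 2923 or divide chromosomes into equal parts were chosen after the data had been seen, though before their own results.

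Chromosome X held 73 regions, and the tables argue against chance placement, whose range began at 335. They also argue against repeated counting of autosomal clusters, since the upper bound of the density ratio was 0.265 when regions within the clustering distance were counted once. A loss of weak regions on X may contribute and stays open, and the number of reads on X is unknown. Of the X regions, 49.3% (exact 95% interval 37.4 to 61.3%) stood after number 2923, the middle of the list. Without such a loss the share would lie near that of all regions, which the interval includes. The rule rejected the loss only if the interval lay wholly below that share, so the test could hardly reject it. The density ratio of X was 0.191 in the first part of the list, against 0.188 over all. X regions were narrower, with a median of 299 bp against 349 bp on the autosomes. The test also takes list order as a rank by strength, which is not stated for this list. Copy number, an inactive X, mappability and gene content were not tested, and the design names no group that bears on a biological explanation.

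The excess of clusters is unlikely to come only from single bound stretches that were split into regions no more than 2 kb apart. With regions within 2 kb merged, 98 clusters remained, above the upper end of 9 in uniform placements. Stretches split by wider gaps would remain after this merging. Density differences over more than 1 Mb also do not account for it alone. Placement of each region in its own 1 Mb window gave at most 36 clusters at the upper end of its range, against 237 observed, although its mean of 25.6 exceeds the 5.30 of uniform placement. Merged regions were not placed in 1 Mb windows, so the joint effect of splitting and such density differences was not tested. Mappability or open chromatin at scales below 1 Mb stays open and was not tested, nor was a biological explanation, for which the design has no group.

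Chromosome 19 was the densest autosome, and repeated counting of clusters does not explain this, as 166 regions remained with those within the clustering distance counted once, against 90 to 131 in uniform placement over the autosomes alone. A gain of the whole chromosome could neither be excluded nor supported. Of its 10 equal parts, 9 held more regions than the median part of the autosomes, but the chromosome was picked for its density, and an even spread of its 204 regions gave 8 or more such parts in 100% of 1000 draws. Gene content was not tested, and the input reads that would bear on copy number were not used here.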
